A study of Mus musculus with 20 samples.

How the data were processed

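The series holds 20 polyA RNA-seq libraries of mouse eWAT, the white adipose tissue of the epididymal fat pad, 10 from a control diet and 10 from random food restriction. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy kit, libraries were made with the Universal Plus mRNA-seq kit of Tecan, and 52-bp paired ends were read on a NovaSeq instrument. The extraction text names QUAD, a usual short form of quadriceps muscle, where the tissue label says eWAT, and the tissue label was used here. The submitters' processing notes name bcl2fastq 4.0.3, STAR, Salmon and the build GRCm38, with no role or order. The deposited table of the authors holds whole-number counts per gene, neither scaled nor filtered as far as its values show, for 55401 genes. The counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical genes (mast cell proteases, class II genes, ribosomal proteins, haemoglobins, immunoglobulin segments) can be split between copies.

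Gene symbols were taken by gene identifier. Of the genes, 55141 had a symbol, 260 had none (0.0086% of all counts) and 213 shared one. Of the versioned identifiers, 54349 (98.1%) were found in GENCODE vM21, a release on GRCm38, and 86.05% had the same coordinates there. Coordinates are given as in the deposited table, 1-based, and span the whole annotated gene, exons and introns. In total 19721 genes were at 0 in all libraries. Replicate numbers name separate libraries of 1 diet.

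Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10, a quasi-likelihood fit with the contamination label and the diet as terms, two-sided tests, and Benjamini-Hochberg adjustment at 0.05. The filter left 15986 genes, which held at least 99.629% of the counts of each library. The same fit gave the genes associated with the contamination label, and a fit with the product of both terms gave the interaction. CPM values of single genes are counts scaled to the total of the tested genes of their library times its TMM factor. Marker sums, and the ranges of Ckm, Myh4 and Ttn, are scaled to the plain library total instead. A ± after a CPM value is the SD over 10 libraries of a group. At totals of 14306528 to 44061508 counts per library, the counting error of genes at 10 CPM or more is small beside the spread between libraries (biological coefficient of variation 0.179), and that of genes near 1 CPM is not.

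In all, 37 gene lists (pathways, cell types and other tissues that the fat pad adjoins) were fixed before the data were examined, as were the tests, the alternatives named as planned and the rule for named genes. Each list was tested by camera of limma 3.58.1 on log2 CPM (prior count 2) against all other tested genes, with a preset correlation of 0.01 and adjustment over the 37 lists. Camera was also run with the correlation estimated per list. A list index is the mean log2 CPM over all listed genes. Indices were compared by two-sided exact permutation tests that kept the contamination label (or the diet) fixed, over 14400 arrangements, with the mean of the differences within the strata as the statistic; the smallest p they can give is 6.94e-05. List counts "adjusted over the list alone" use the p-values of the list's measured members only.

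Genes are named by this rule. Named were up to 12 higher and 12 lower genes with the largest log2 fold change among those called by diet, with a mean of at least 1 CPM in a diet, the same sign in libraries marked No alone and Yes alone, and a proper gene name. Named too were up to 4 members with the smallest p of each list, the 6 genes with the smallest p in each direction for the contamination label, and Lep, Adipoq, Ucp1, Pparg, Fasn and Pck1. Clock, Csf3r, Cxcl12, Lum, Col1a2, Eln, Dhcr7, Srebf2, Angptl4, Akt2 and Npr3 complete small counts and were named after their values were seen.

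The alternatives tried were DESeq2 1.42.0, RLE and upper-quartile factors, other filters on low counts, limma-voom with quality weights, a surrogate variable (sva 3.50.0), models without the label, with indices of germ cells and epididymis in its place or with the RNA integrity number, libraries marked No or Yes alone, removal of label-associated genes, a replicate block, and leaving out each library. Added after the data were seen were a skeletal muscle index as a term, 14 libraries without the 6 that held muscle transcripts, the fry test, permutation tests of every list index, lists in libraries marked Yes alone, 17 libraries without the integrity term, lists and indices without each library, and an estimated correlation for lists by label. Indices and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: of 200 changed among 15839 genes, 60% of the 1.5-fold and 84% of the 2-fold changes were recovered, 6 of 161 calls were false (3.73%), and the moved list was found with 0 false lists. Each gene was simulated independently of the others, so the 0 false lists cannot speak for lists whose genes vary together. Library sizes were totals of the tested genes in edgeR and camera, and totals of all genes in the indices and marker sums.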

Results

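PolyA RNA was sequenced from mouse eWAT, the fat pad that lies on the epididymis, in 20 libraries. Per the labels, 10 came from a control diet and 10 from random food restriction, a regime of intermittent fasting combined with 5% calorie restriction. The series is presented as a study of food insecurity and fat mass, and the design implies the question of which transcripts of this depot differ between the diets. The labels also mark libraries as contaminated with spermatocytes, the meiotic germ cells of the testis: Yes for 7 control and 3 restricted libraries, No for 3 control and 7 restricted. Libraries held 14306528 to 44061508 counts, on average 23815428 ± 7421430 in control and 25599190 ± 7233981 in restricted libraries (SD, n = 10 each). The RNA integrity number was 7.41 ± 0.267 in control (SD, n = 9) and 7.18 ± 0.399 in restricted libraries (SD, n = 8). Scd1, a fatty acid desaturase, was the most abundant gene of each library and took 3.09% to 8.07% of its counts. In a principal component analysis of log2 CPM, the first component held 44.5% of the variance and parted the libraries by the contamination label, from −56.29 to −12.47 for Yes and from 24.07 to 48.84 for No; the second held 9.30%. Skeletal muscle transcripts stood apart in 6 libraries, Control 1 to 5 and Restricted 1, with a muscle index of 3.73 to 5.77 log2 CPM against −0.328 to 1.37 in the other 14. The other 14 are called libraries without muscle transcripts below, though traces stayed. Restricted 10 had the 1.37, with Ckm at 2.81 and Myh4 at 7.51 CPM. No library pair of a diet was within sampling noise of each other (chi-square per degree of freedom at least 9.45). The labels do not say whether libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

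Restriction was followed by lower levels of 19 of 26 macrophage genes and 7 of 9 genes of antigen presentation. Lower too were 4 mast cell proteases and 5 of 20 progenitor genes. Higher were 7 of 8 mitochondrially encoded genes and 7 of 25 lysosomal genes. Of 19 genes of the circadian clock, 11 rose and 2 fell. Mcpt4, a mast cell protease, fell from 11.3 ± 2.46 to 4.01 ± 0.737 CPM, and Bmper, a regulator of bone morphogenetic proteins made by progenitor cells, fell from 70.8 ± 10.3 to 28.4 ± 6.59 CPM (SD, n = 10 each). Scd1 rose from 34890 ± 3290 to 62720 ± 17700 CPM. In edgeR's quasi-likelihood test with the label in the model, 2173 of 15986 genes changed with diet, 1008 higher and 1165 lower, and 4517 had an unadjusted p under 0.05. Of the calls, 133 were at least 2-fold, 55 higher and 78 lower. All but 1 of the 2173 had the same sign in libraries marked No alone and in those marked Yes alone. That is no separate test, since the same libraries chose these genes. The count was 423 in libraries marked No alone, 293 in those marked Yes alone, 929 without the 6 libraries with muscle transcripts, and 411 with the RNA integrity number in a model of 17 libraries (1461 in the same 17 without it). Of the 37 lists, 21 passed camera's test, 11 up and 10 down. With an estimated correlation only 3 lists passed (macrophages, neutrophils and mast cells, circadian clock), without the 6 libraries with muscle transcripts 9 passed and without Restricted 1 14 passed, and other splits of the libraries gave up to 26.

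**Figure D1:**
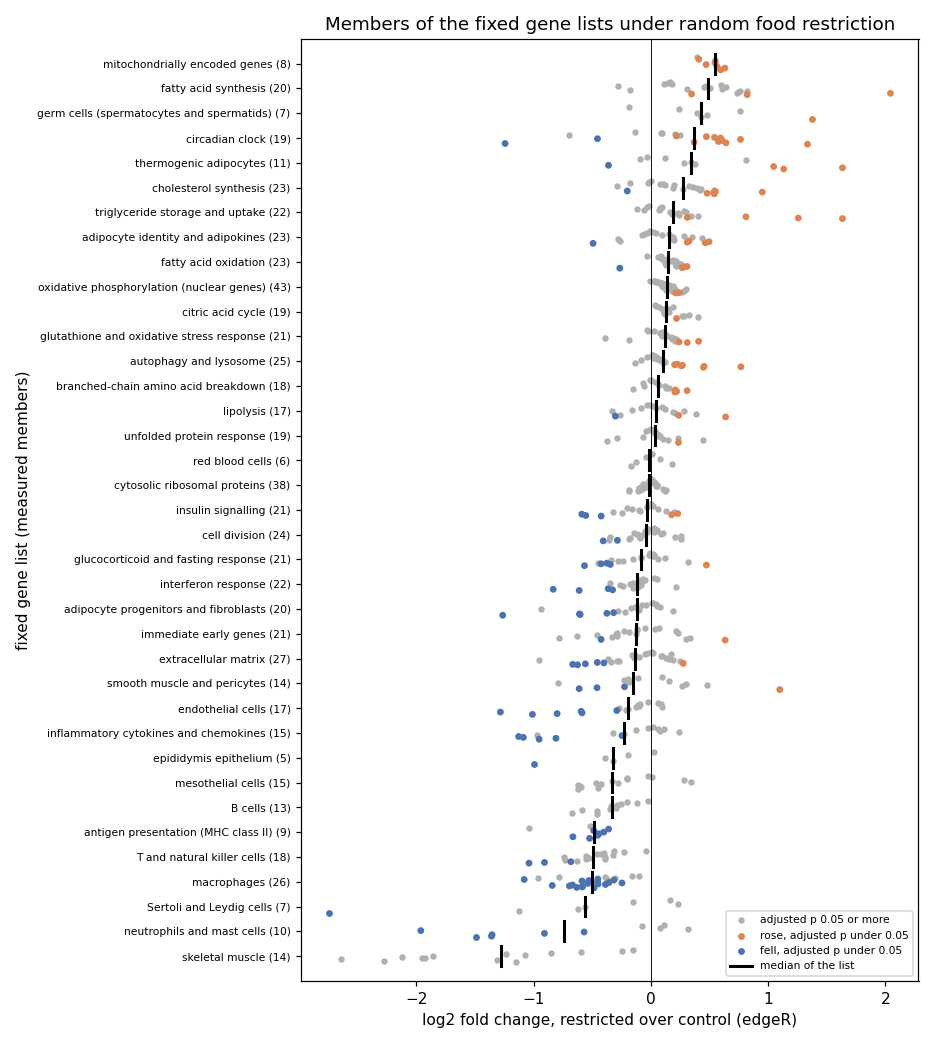
Each point is the log2 fold change (restricted over control, edgeR) of a measured member of 1 of the 37 gene lists, coloured where it rose or fell at an adjusted p under 0.05, and each black bar is the median of its list. The medians run from −1.28 for skeletal muscle, with no member called, to 0.55 for mitochondrially encoded genes.

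Immune cell genes were lower in restricted libraries. Of 26 macrophage genes, 19 fell and 0 rose (0 rose and 23 fell adjusted over the list alone), with a median log2 fold change of −0.51 (adjusted p = 1.22e-15, and adjusted p = 0.0257 with an estimated correlation). Cd68, a lysosomal membrane protein of macrophages, went from 46.3 ± 4.99 to 34.6 ± 2.96 CPM (log2 fold change −0.49 ± 0.0579 SE, adjusted p = 3.71e-05). Csf1r, the receptor that macrophages need to survive, went from 234 ± 27.9 to 161 ± 21.3 CPM, and Clec10a, a lectin of macrophages and dendritic cells, fell by 0.63 on the log2 scale (adjusted p = 5.81e-05). The macrophage index was 4.54 to 4.96 in the 10 restricted libraries and 5.04 to 5.40 in the 10 control libraries (exact permutation p = 6.94e-05, the smallest the test can give). Of 9 genes of antigen presentation by class II molecules, 7 fell and 0 rose (9 fell adjusted over the list alone; median −0.49, adjusted p = 4.6e-08, and adjusted p = 0.0924 with an estimated correlation). Among them, Cd74, the invariant chain, went from 987 ± 92.7 to 697 ± 80.2 CPM, and Ciita, the transactivator of the class II genes, had a log2 fold change of −0.67 (adjusted p = 0.00102). Of 10 measured genes of neutrophils and mast cells, 6 fell and 0 rose (6 fell adjusted over the list alone; median −0.74, adjusted p = 2.2e-05, and adjusted p = 0.0433 with an estimated correlation). The fallen members were the mast cell proteases Mcpt4, Tpsb2, Cma1 and Cpa3, with log2 fold changes from −1.49 to −0.91, and the neutrophil genes Csf3r and Camp.

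Other immune lists had fewer calls. Of 18 genes of T and natural killer cells, 3 fell and 0 rose, the same counts adjusted over the list alone (median −0.50, adjusted p = 0.0012, and adjusted p = 0.364 with an estimated correlation). Cd4, the co-receptor of helper T cells, went from 2.24 ± 0.785 to 1.08 ± 0.371 CPM. The other two, Cd5 and Il7r, missed the threshold without 3 and 16 of the libraries taken singly, up to an adjusted p of 0.0754 and 0.143 without Control 6. Of 15 cytokine and chemokine genes, 5 fell and 0 rose (6 fell adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.267 with an estimated correlation). They include Nlrp3, an inflammasome sensor (log2 fold change −0.95), Ccl5 (−0.81), Il1rn, which blocks the interleukin 1 receptor (−1.09), Cxcl12, and Ccl8, whose −1.13 became −0.93 without Control 6 (adjusted p = 0.0924). In the 14 libraries without muscle transcripts, Il1rn was at −0.64 (adjusted p = 0.18) and Ccl8 at −1.24 (0.0567), and 2 of the 15 were called lower. Of 22 interferon response genes, 4 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.572 with an estimated correlation); Mx1 fell by 0.61, while Ifit2, Oas3 and Isg15 missed the threshold without 4, 9 and 12 single libraries. The interferon response index differed by −0.02 in libraries marked No and by −0.34 in those marked Yes, and the list had an adjusted p of 0.945 in libraries marked No alone and of 0.104 without Restricted 2. None of the 13 genes of B cells passed by itself (0 rose and 0 fell adjusted over the list alone), while the list did at a median of −0.34 (adjusted p = 0.0121, and adjusted p = 0.572 with an estimated correlation). The B cell list did not pass without Restricted 1 (adjusted p = 0.0972) or without Restricted 3 (0.0504). In the 14 libraries without muscle transcripts, the macrophage, class II, neutrophil and mast cell, and T cell lists still passed, and adjusted p was 0.143 for cytokines, 0.0956 for interferon response and 0.682 for B cells. With the RNA integrity number in a model of 17 libraries, the mean log2 fold change of the macrophage list was −0.42 against −0.50 without it.

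**Figure D2:**
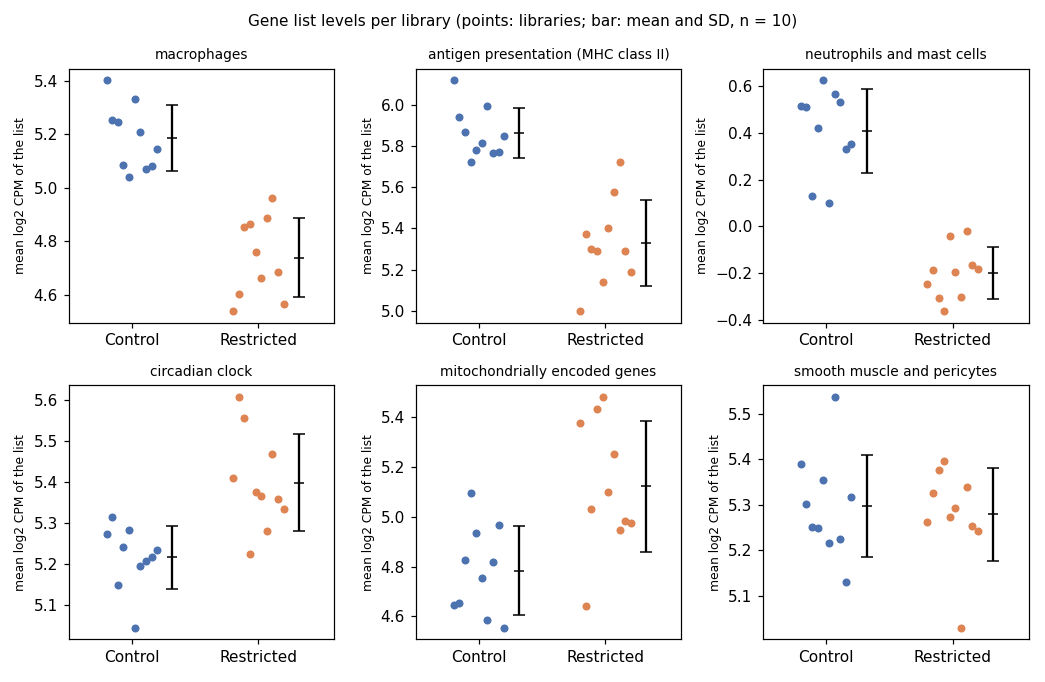
Each point is the index (mean log2 CPM) of a gene list in 1 library, for 6 lists and both diets, and each bar shows the mean and SD over 10 libraries. All restricted libraries lie below all control libraries for macrophages and for neutrophils and mast cells, and the diets overlap for smooth muscle and pericytes.

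Some genes of progenitor cells, matrix and vessels were lower as well. Of 20 genes of adipocyte progenitors and fibroblasts, 5 fell and 0 rose (6 fell adjusted over the list alone; adjusted p = 0.00308, and adjusted p = 0.304 with an estimated correlation). Besides Bmper, whose log2 fold change was −1.26 ± 0.121 (SE, adjusted p = 5.29e-06), Dcn, the proteoglycan decorin, went from 1297 ± 113 to 884 ± 104 CPM, and the progenitor receptor Pdgfra from 81.7 ± 11.2 to 54.2 ± 6.69 CPM. Icam1 (−0.38) and Lum completed the 5. In the 14 libraries without muscle transcripts, adjusted p was 0.0851 for this list and for extracellular matrix. Of 27 extracellular matrix genes, 5 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.0481, and adjusted p = 0.572 with an estimated correlation); this call ended without any of 10 single libraries. Mmp2 and Mmp14, which degrade matrix, fell by 0.63 and 0.67, fibronectin (Fn1) by 0.56, and Col1a2 and Eln by less, while Sparc rose from 2872 ± 168 to 3517 ± 356 CPM. Of 17 endothelial genes, 6 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.572 with an estimated correlation), and without Control 7 the list had an adjusted p of 0.0574. Plvap, of fenestrated vessels, went from 42.2 ± 15.9 to 25.2 ± 4.96 CPM. Lyve1, which is also on the macrophage list and counted there, fell by 0.59, with an adjusted p of 0.0577 without Control 3. Prox1, the transcription factor of lymphatic vessels, fell by 1.28 (adjusted p = 0.015), and by 0.91 without Control 7 (adjusted p = 0.0893). Vwf fell by 1.01, and by 0.67 without Control 7, where it still passed. Among 14 genes of smooth muscle and pericytes, 1 rose and 3 fell (4 rose and 3 fell adjusted over the list alone) and the list did not pass (adjusted p = 0.843). Cspg4, a pericyte proteoglycan, rose from 60.3 ± 14.9 to 125 ± 50.9 CPM (log2 fold change 1.10). In the 14 libraries without muscle transcripts its log2 fold change was 0.67 (adjusted p = 0.065). Without Control 7 the adjusted p of Lmod1, Myh11 and Smtn, which fell, was 0.0572, 0.0791 and 0.0866.

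Lists of lipid synthesis and storage passed in the 20 libraries, and each of them rested on Restricted 1, which also held muscle transcripts. Of 20 genes of fatty acid synthesis, 3 rose and 0 fell (4 rose adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.59 with an estimated correlation). They were Scd1 (log2 fold change 0.82 ± 0.147 SE, adjusted p = 0.000989), the elongase Elovl5 (0.35, adjusted p = 0.00822) and the elongase Elovl6. Elovl6 went from 55.1 ± 17.3 to 183 ± 233 CPM (adjusted p = 0.00833), and without Restricted 1 its log2 fold change was 0.90 (adjusted p = 0.32). In the 14 libraries without muscle transcripts, Scd1 had a log2 fold change of 0.59 (adjusted p = 0.0548). Restricted 10, which held a trace of muscle transcripts, was among the 14. Of 22 genes of triglyceride storage and uptake, 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00308, and adjusted p = 0.572 with an estimated correlation). Cidea, a lipid droplet protein, went from 3.50 ± 1.2 to 10.8 ± 7.8 CPM, and the fatty acid carrier Fabp4 from 9988 ± 810 to 12560 ± 1460 CPM. Mogat2 had a log2 fold change of 1.26, and of 0.72 without Restricted 1 (adjusted p = 0.0479), and Fabp5 of 0.81, and of 0.20 without it (adjusted p = 0.415). Of 23 genes of cholesterol synthesis, 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.575 with an estimated correlation). Fdft1, squalene synthase, rose from 78.7 ± 8.41 to 114 ± 18.4 CPM, Sc5d by 0.48 and Dhcr7 by 0.55 on the log2 scale, and Srebf2 fell. Insig1 had a log2 fold change of 0.95, and of 0.42 without Restricted 1 (adjusted p = 0.227). Without Restricted 1, adjusted p was 0.648 for fatty acid synthesis, 0.151 for triglyceride storage and 0.651 for cholesterol synthesis; the first also missed the threshold without Restricted 10 (0.0515). Of 17 lipolysis genes, 2 rose and 1 fell (2 rose and 2 fell adjusted over the list alone; adjusted p = 0.346), and Adora1, the adenosine receptor that restrains lipolysis, rose from 106 ± 11.6 to 165 ± 33.5 CPM. Prkar2b and Npr1, the other two, missed the threshold without 11 and 3 single libraries.

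**Figure D3:**
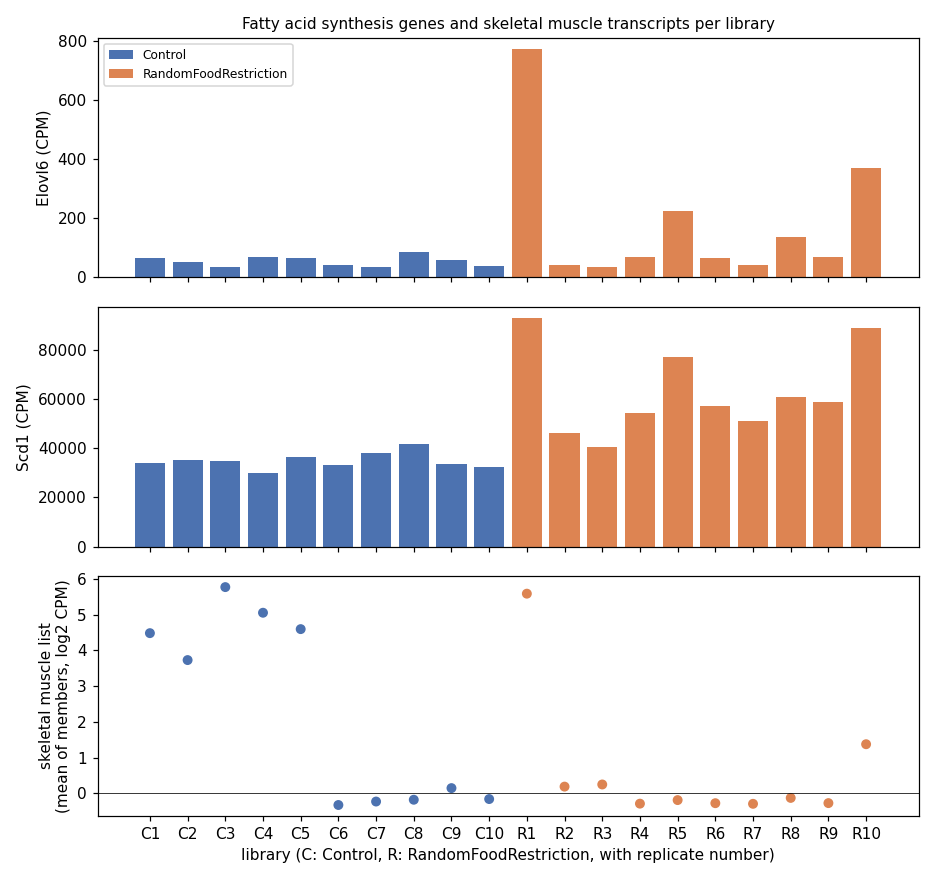
Bars show the CPM of Elovl6 and of Scd1, and points the skeletal muscle index (mean log2 CPM), in each of the 20 libraries, coloured by diet. Elovl6 reached 773 CPM in Restricted 1, 372 in Restricted 10 and 224 in Restricted 5, and the muscle index was above 3 in Control 1 to 5 and Restricted 1.

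Mitochondrially encoded genes rose. Of 8 measured, 7 rose and 0 fell, also adjusted over the list alone (median log2 fold change 0.55, adjusted p = 2.2e-05, and adjusted p = 0.304 with an estimated correlation). mt-Co1, a subunit of cytochrome oxidase, went from 7582 ± 1210 to 11950 ± 2400 CPM (adjusted p = 0.00341), and mt-Nd4, of complex I, from 1870 ± 278 to 2854 ± 521 CPM. Of 43 nuclear genes of oxidative phosphorylation, 2 rose and 0 fell (0 rose adjusted over the list alone) at a median of 0.14 (adjusted p = 0.000104, and adjusted p = 0.572 with an estimated correlation). Those 2, Atp5j and Uqcrfs1, had log2 fold changes of 0.21 and 0.24, and missed the threshold without 8 and 10 single libraries. Of 23 genes of fatty acid oxidation, 3 rose and 1 fell (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.00206, and adjusted p = 0.572 with an estimated correlation). Hadh rose from 408 ± 28.2 to 494 ± 58.8 CPM, and Cpt1a, which controls the entry of fatty acids into mitochondria, fell from 131 ± 9.12 to 107 ± 12.3 CPM. Acadl and Decr1 also rose, with an adjusted p of 0.0595 and of 0.0569 without Restricted 1. The citric acid cycle list passed with 1 riser among 19 genes, Sucla2, itself lost without 16 single libraries (0 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.59 with an estimated correlation). Branched-chain amino acid breakdown passed with 4 of 18 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0342, and adjusted p = 0.572 with an estimated correlation), with Hibadh (0.20), Bckdhb (0.22), Hibch (0.31) and Auh, which missed the threshold without Restricted 1 (adjusted p = 0.0808) or Control 7 (0.0511). Without Restricted 1, adjusted p was 0.109 for oxidative phosphorylation, 0.125 for fatty acid oxidation, 0.651 for the citric acid cycle and 0.142 for branched-chain amino acids. The last also missed the threshold without Control 1, Control 7, Restricted 5 or Restricted 10. The mitochondrially encoded list passed without each single library.

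Clock genes differed in both directions. Of 19, 11 rose and 2 fell (12 rose and 2 fell adjusted over the list alone; median log2 fold change 0.37, adjusted p = 0.000116, and adjusted p = 0.00851 with an estimated correlation). Ciart, a repressor of the clock, rose from 8.40 ± 2.58 to 19.5 ± 5.23 CPM, and Arntl, the activator also called Bmal1, fell from 4.54 ± 1.22 to 1.76 ± 0.67 CPM (log2 fold change −1.24 ± 0.193 SE, adjusted p = 0.000293). The output factors Hlf and Tef rose by 0.64 and 0.37, and Clock, the partner of Arntl, was the other gene that fell. The sample values used here hold no time of collection, so clock genes could not be compared at a known time of day. Of 25 genes of autophagy and the lysosome, 7 rose and 0 fell (8 rose adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.304 with an estimated correlation). The protease Ctsd went from 933 ± 99.9 to 1595 ± 555 CPM, Ctsl from 476 ± 39.5 to 655 ± 92.8 CPM and the sterol carrier Npc2 from 668 ± 65.9 to 931 ± 167 CPM. In the 14 libraries without muscle transcripts 1 of the 25 was called, Ctsd had a log2 fold change of 0.50 against 0.77 (adjusted p = 0.137), and Npc2 an adjusted p of 0.0769. Of 21 glutathione and oxidative stress genes, 3 rose and 0 fell (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.304 with an estimated correlation), an adjusted p of 0.0673 in the 14 libraries, Gsta4 at 0.31, and Gstm1 and Gpx4 lost without 2 and 7 single libraries. Of 21 glucocorticoid and fasting genes, 1 rose and 4 fell (1 rose and 5 fell adjusted over the list alone; adjusted p = 0.15); Zbtb16 fell by 0.57 and Angptl4, which inhibits lipoprotein lipase, by 0.38, while Txnip, Dusp1 and the riser Per1 missed the threshold without 4, 13 and 2 single libraries. Of 21 insulin signalling genes, 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.3). Irs1, the insulin receptor substrate, fell from 39.9 ± 4.89 to 30.3 ± 4.66 CPM and Akt2 rose by 0.23, while Grb14, Socs3 and Grb10 missed the threshold without 2, 3 and 4 single libraries. The index of this list dropped by 0.10 in restricted libraries (exact permutation adjusted p = 0.00771).

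Adipocyte genes moved little as a list. Of 23, 4 rose and 1 fell (4 rose and 2 fell adjusted over the list alone; adjusted p = 0.132). Lep, the gene of leptin, went from 1065 ± 230 to 1500 ± 348 CPM (log2 fold change 0.50 ± 0.147 SE, adjusted p = 0.0292). Its adjusted p was 0.0525 without Restricted 2, 0.086 without Restricted 3, 0.0534 without Control 6 and 0.071 without Control 7. Trarg1, a regulator of glucose transporter traffic, rose from 608 ± 120 to 843 ± 112 CPM, Npr3 rose by 0.33, Fabp4 rose as above, and Acvr1c, an activin receptor of adipocytes, fell from 146 ± 25 to 114 ± 20.3 CPM. Log2 fold changes were 0.18 for Adipoq (adjusted p = 0.14), 0.20 for Pparg (0.101), 0.64 for Fasn (0.215) and 0.09 for Pck1 (0.698), none past the threshold. Ucp1, the uncoupling protein of brown fat, had 0 to 3 counts per library, too few to test. The thermogenic list had 3 of 11 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0583), while its index was higher by 0.28 in restricted libraries (exact permutation adjusted p = 0.046): the potassium channel Kcnk3 rose from 20.5 ± 4.69 to 44.5 ± 14.5 CPM, Cidea rose, Ebf2 fell by 0.36, and Cox8b was at 1.05, and at 0.72 without Restricted 1 (adjusted p = 0.0639). Other lists did not pass: skeletal muscle (median −1.28, 0 of 14 called, adjusted p = 0.0607), mesothelial cells (0 of 15, 0.142), Sertoli and Leydig cells (1 of 7 lower and 2 adjusted over the list alone, 0.0859), cell division (2 of 24 lower, also adjusted over the list alone, 0.185), immediate early genes (1 of 21 higher and 1 lower, 0 adjusted over the list alone, 0.17), the unfolded protein response (1 of 19 higher, 0 adjusted over the list alone, 0.3), ribosomal proteins (0 of 38, 0.368) and red blood cells (0 of 6, 0.97).

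Among the genes with the largest changes, several did not overlap between the diets. Fgf13, an intracellular relative of the fibroblast growth factors (ENSMUSG00000031137.17, chromosome X, 59062145 to 59568071, GRCm38), rose from 4.60 ± 1.99 to 15.0 ± 5.68 CPM (log2 fold change 1.69 ± 0.245 SE, adjusted p = 0.000146). Lctl, a lactase-like protein (chromosome 9, 64117147 to 64138105), rose from 14.1 ± 5.34 to 40.1 ± 11.6 CPM, and the trafficking protein Mal2 and the exchange factor Plekhg6 rose by 1.45 each. Restricted levels of these 4 lay above control levels in all libraries. Slc2a5, the fructose transporter, rose by 1.66 (adjusted p = 0.011), Ntsr2, a neurotensin receptor, by 1.45 (0.000893), and Cidea (chromosome 18, 67343604 to 67367785) by 1.63 (0.00491). In the 14 libraries without muscle transcripts these 3 missed the threshold, with adjusted p 0.135 for Slc2a5, 0.0706 for Ntsr2 (log2 fold change 0.90) and 0.147 for Cidea. The other largest risers leaned on Restricted 1. Without it, the log2 fold change went from 2.97 to 1.12 for the ferroxidase Hephl1 (adjusted p = 0.315), from 1.43 to 0.28 for Podnl1 (0.722), from 1.79 to 0.92 for AC151478.3 (0.161) and from 1.37 to 0.91 for the meiotic gene Sycp3 (0.0017). Podnl1 was also lost without 13 other libraries. Downward, Col6a5, a collagen chain (chromosome 9, 105856078 to 105960643), fell from 246 ± 92.9 to 64.3 ± 22 CPM with no overlap (log2 fold change −1.86 ± 0.236 SE, adjusted p = 5.55e-05). Hpca, a neuronal calcium sensor (chromosome 4, 129111570 to 129122036), went from 10.3 ± 5.76 to 2.04 ± 1.06 CPM, and its neighbour Fndc5, the precursor of irisin (129136999 to 129144593), went from 7.04 ± 3.7 to 1.87 ± 1.39 CPM (adjusted p = 0.00173). Mmrn1 fell from 14.5 ± 7.8 to 3.63 ± 2.04 CPM, Reln by 1.77, Cd7 by 1.79, the chemokine Ccl17 by 1.72 and the antimicrobial Camp by 1.96. Without Control 7, Cldn11 went from −2.74 to −1.74 (adjusted p = 0.0657), Art4 from −1.84 to −1.45 (0.0565) and Duox2 from −1.65 to −1.13 (0.0606). Igkv1-117, a segment of the kappa light chain (−2.15, adjusted p = 0.0437), was lost without 12 of the libraries taken singly, up to an adjusted p of 0.155 without Control 6. Of 180 named genes, 54 were found to have exons that overlap another gene, so their counts are uncertain. A stated strand setting would help only with overlaps on the opposite strand. Such overlaps concern Elovl6, Lctl, Sycp3, Hpca, Cd7 and Reln. Among genes above they concern Csf1r, Ciita, Pdgfra, Icam1, Fn1, Prox1, Smtn, Mogat2, Adora1 and Npr1. They also concern mt-Co1, Atp5j, Arntl, Tef, Ctsl, Txnip, Dusp1, Irs1, Acvr1c, Kcnk3 and Ebf2. Ctsb overlaps Fdft1 on the opposite strand, so the count of Fdft1 is uncertain as well. Overlaps on the same strand concern Cd74, Ctsd, Ctsl, mt-Nd4, Hibadh and Pdgfra.

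The contamination label went with genes of motile cilia and of epithelium. The comparison asks which transcripts the label marks. Rsph4a, of the radial spokes of cilia (chromosome 10, 33905111 to 33916021), was at 0.106 ± 0.107 CPM in libraries marked No and 5.47 ± 2.56 CPM in those marked Yes (SD, n = 10 each; log2 fold change 6.01 ± 0.355 SE, adjusted p = 4.8e-10). Hnf4a, a transcription factor of absorptive epithelia (chromosome 2, 163506808 to 163572910), was at 0.161 ± 0.149 and 11.3 ± 5.44 CPM, and Cfap44, of the ciliary axoneme, at 0.402 ± 0.32 and 15.6 ± 6.48 CPM. The ciliary genes Hydin and Tcte1 and the glycosyltransferase B4galnt3 were higher by 4.56, 6.81 and 5.71, and Hydin, Tcte1 and B4galnt3 overlap a gene on the opposite strand. In edgeR's quasi-likelihood test, 848 genes differed by label, 805 higher and 43 lower in libraries marked Yes, and 562 at least 2-fold, 559 of them higher. The lower genes moved less: Ermp1 −0.22, Ntf3 −0.64, Sema5a −0.42, Man2a1 −0.23, Rapgef5 −0.34 and Isl1 −1.28. Of the genes called by diet, 78 were also called by label. By label, 8 lists passed camera at the preset correlation and 0 with an estimated correlation. At the preset correlation the germ cell list was up (2 of 7 called higher, adjusted p = 0.0175, and 0.611 with an estimated correlation), as were ribosomal proteins (4 of 38, median 0.16, 2.59e-09 and 0.611), while the macrophage (0.00575) and interferon lists (0.00285) were down with 0 members called, each at 0.611 with an estimated correlation.

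**Figure D4:**
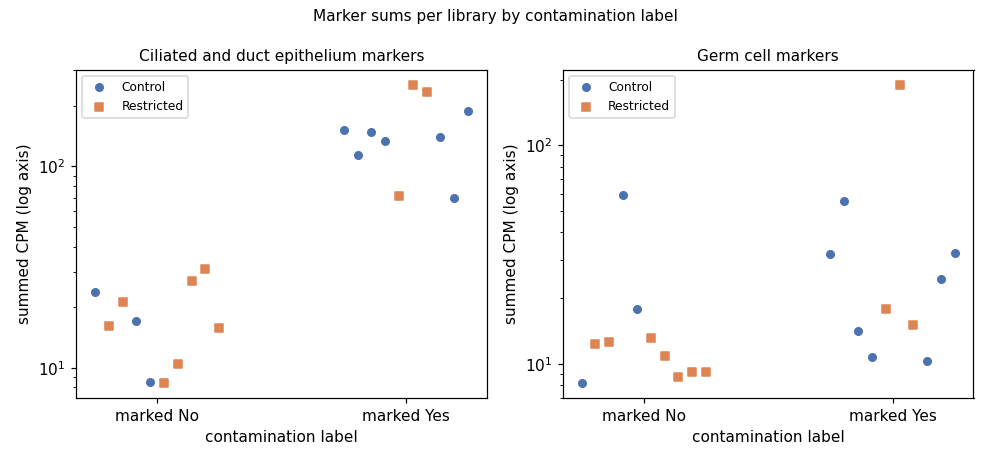
Each point is the summed CPM of marker genes in 1 library, on a log axis, by contamination label, with ciliated and duct epithelium markers (chosen after the label's genes were seen) on the left and germ cell markers on the right. The epithelial sums were 70 to 254 CPM for Yes and 8.42 to 30.9 for No, and the germ cell sums 10.3 to 190 and 8.18 to 59.4.

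Germ cell and epididymis transcripts were set against the label and the diet with indices over all listed genes. The germ cell index was −1.10 ± 1.18 log2 CPM in libraries marked Yes and −2.16 ± 0.811 in those marked No (SD, n = 10 each). The difference within diets was 0.89 (exact permutation p = 0.0845, adjusted over 3 tests 0.254), 0.21 in control and 1.57 in restricted libraries. Without Restricted 2 it was 0.29, and without Control 6 it was 1.21 (exact permutation p = 0.0183). By diet the germ cell index differed by −0.43 (exact permutation p = 0.395), from −2.02 ± 1.24 in restricted to −1.24 ± 0.895 in control libraries. It was −1.11 in libraries marked No and 0.25 in those marked Yes, and without Restricted 2 it was −1.03 (exact permutation p = 0.00972). Camera's 7 measured members of the germ cell list had a mean of 0.50 by diet, opposite in sign to the index (1 of 7 higher, also adjusted over the list alone; adjusted p = 0.15). The epididymis index was −2.23 ± 0.306 in restricted and −1.54 ± 1.19 in control libraries, a difference of −0.69 (exact permutation p = 0.174, adjusted 0.261), and −0.15 without Control 6. Of the 5 measured epididymis genes 1 fell, also adjusted over the list alone: Sult1e1, a sulfotransferase that acts on estrogen, from 64.2 ± 11.6 to 31.8 ± 9.67 CPM (list adjusted p = 0.0741).

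The design also allows the question of whether the diet effect differs between libraries marked Yes and No. Macrophage, class II and mast cell genes fell in both: the macrophage index differed by −0.49 in libraries marked No and by −0.49 in those marked Yes, and the clock index by 0.21 and 0.27. Of 15986 genes, 0 passed edgeR's interaction test, 871 had an unadjusted p under 0.05, and DESeq2 called 1. The smaller group of each label held 3 libraries, and the size of difference the test could find was not examined here.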

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

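Of the tests below, those of germ cell RNA, of diet and table position for muscle transcripts, and of muscle RNA and the share of other cells for immune genes were chosen after the results were seen. In 18 of 140 groups of 10 libraries, 1 library stood apart by a gap large against the whole range of its group. For normally distributed values chance gives about 1 in 20, or 7 groups. Single genes were tested as plain CPM, and most were chosen for large changes in these libraries, so an excess over 7 is no separate evidence. Restricted 1 stood apart from the other restricted libraries for Hephl1 (29.4 CPM, next 5.57; gap over range 0.816), Elovl6 (773, next 372; 0.543), AC151478.3 (7.56, next 3.77; 0.542), Podnl1 (15.9, next 6.19; 0.641) and Sycp3 (12.6; 0.66). It also had the highest cholesterol synthesis index (0.478) and skeletal muscle index (0.716) of its diet. Restricted 2 stood apart in the germ cell index (1.46 log2 CPM, next −1.99; 0.83) and in the index of Sertoli and Leydig cells (0.662). Among control libraries, Hpca (24.8 CPM, next 13.9; 0.508) and its neighbour Fndc5 (15.9, next 10.2; 0.469) were highest in Control 2, Cldn11 in Control 7 (6.05, next 3.22; 0.477), Igkv1-117 in Control 1 (9.91, next 3.55; 0.646) and Hephl1 in Control 8 (2.42, next 1.40; 0.493). Control 6 had the lowest index of ribosomal proteins (0.571) and Restricted 7 the lowest of smooth muscle and pericytes (0.58). Camp was highest in Restricted 5 among restricted libraries (0.826 CPM; 0.632), and Restricted 9 had the highest total of its diet (44061508 counts, next 27872919; 0.628).

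Genes higher in libraries marked Yes: RNA of spermatocytes and spermatids predicts germ cell markers above the other libraries, yet only 1 of 10 libraries marked Yes lay above every library marked No in their summed CPM (10.3 to 190 against 8.18 to 59.4), and 5 did without Control 6, the highest marked No (next 17.9), which argues against this as the whole source. RNA of a ciliated and absorptive duct epithelium was tested on 19 epithelial genes chosen without seeing their values: all 10 libraries marked Yes lay above every library marked No (35.8 to 143 against 5.19 to 18.2 CPM), and 15 of 16 tested genes were called higher, 0 lower. Cdh16 was at 22.3 ± 9.14 CPM for Yes and 0.419 ± 0.796 for No (SD, n = 10 each), and Ak7 at 6.07 ± 2.84 and 0.111 ± 0.23. These values are consistent with RNA of a duct epithelium near the testis, a hypothesis formed after the label's genes were seen, and which duct it is was not tested. The label gives no biological group to set against it. What the label rests on is not stated. If it was set from these counts, a clean parting by it is no separate evidence.

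Skeletal muscle transcripts in 6 libraries: Ckm was at 54.9 to 187 CPM in Control 1 to 5 and Restricted 1 against 0 to 2.81 in the other 14, Myh4 at 136 to 546 against 0 to 7.51, and Ttn at 196 to 1930 against 0.544 to 7.27. Diet was tested by a count: 5 control libraries had a muscle index no higher than that of the 9 lower restricted libraries. That count follows from how the 6 were picked and by itself decides nothing. The index was 3.73 to 5.77 in Control 1 to 5 and −0.328 to 0.145 in the other 5 control libraries. It was 5.59 in Restricted 1 and at most 1.37 in the other 9 restricted libraries. Such gaps within both diets argue against diet as the whole cause, and diet as a part of the cause stays open. RNA of skeletal muscle predicted that other muscle genes rise as well, and 84.2% (16 of 19) were higher in each of the 6 than in each of the other 14, at 0.132% to 0.442% of counts in muscle genes against at most 0.0198%. A step shared by libraries that stand next to each other in the deposited table stays open: the 6 form 1 unbroken run there. Chance gives such a run with a probability of 0.000387 if all places are alike. The table stands in blocks of 1 diet, with Control 1 to 5 first and Restricted 1 to 5 next. A part played by diet would make a run more likely, so this probability cannot tell the 2 apart. Whether the muscle RNA came from tissue or from handling cannot be told from these counts, and the extraction text names QUAD, a usual short form of quadriceps muscle.

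Lower immune markers under restriction: muscle RNA in 6 libraries is argued against as the cause, since the macrophage list passed without them (adjusted p = 2.87e-11, mean −0.44 log2 CPM against −0.49 with all libraries; the range over all alternatives was 1.01e-17 to 0.0257). A lower share of all cells other than adipocytes stays open as a cause. The macrophage minus smooth muscle index was lower under restriction (−0.54 ± 0.177 against −0.11 ± 0.142, SD, n = 10 each, exact permutation p = 0.000139). Smooth muscle genes moved both ways, so their mean is no measure of the other cells. The 14 blood endothelial genes had a median log2 fold change of −0.12, with 3 lower and 0 higher, against −0.51 for macrophage genes. They are the endothelial list without its lymphatic genes, which were set apart after their falls were seen. The full endothelial list had a mean log2 CPM difference of −0.28 against −0.49 for macrophages. In the 14 libraries without muscle transcripts these were −0.35 and −0.44. An equal loss of all other cells would lower both alike. The gap changed with the genes and libraries used, so it cannot decide whether such a loss was the whole cause. Progenitor and endothelial lists were lower too, so a loss, equal or smaller, stays open. RNA integrity as the cause is argued against by the 84.5% of the macrophage list's mean change that stayed with the RNA integrity number in the model of 17 libraries (adjusted p = 5.11e-12). The values are consistent with fewer macrophages, or with less of these transcripts per cell, under restriction, a hypothesis that these data leave open. Contamination is unequal between the diets, and the macrophage list passed in libraries marked No alone (adjusted p = 1.43e-09) and marked Yes alone (2.6e-14).

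Other splits of the 20 libraries bear on the counts, with 100 splits each, the real one included. As many genes changed by diet were found in 1 of 100 splits, the real one (2173, highest other 47). The same held for the genes associated with the contamination label (1 of 100, 848 genes, highest other 409). With 100 splits no share under 1 in 100 can be found, so chance is unlikely for the diet count but not excluded. The labels do not say what the contamination label rests on. If it was set from these counts, its calls follow from that, so the split decides nothing for the label. As many fixed lists changed by diet were found in 5 of 100 splits (21, highest other 26), so chance stays open there. For the interaction (100 of 100; 0, highest other 2) chance is not excluded either, since a real count of 0 is reached by any split.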

How the results depend on the processing

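The muscle index, the 14-library fits, the fry test, list permutations, lists in libraries marked Yes, 17 libraries without the integrity term, and lists and indices under libraries left out were added after the data were seen; the others were planned. Against 2173 genes changed by diet (46.4% higher), counts were 1343 with germ cell and epididymis indices for the label (1243 shared), 411 with the RNA integrity number (405 shared; 17 libraries, and 1461 in the same 17 without that term), 423 in libraries marked No only (30.5% higher; 376 shared) and 293 marked Yes only (30% higher; 266 shared), where fewer libraries were tested, and 929 without the 6 libraries with muscle transcripts (771 shared). DESeq2 gave 2616 and limma-voom 2150. Leaving out 1 library gave 1514 (Control 7) to 2297 (Restricted 7) genes. Against 21 lists, 3 passed with the correlation estimated per list (macrophages, neutrophils and mast cells, circadian clock), 9 without the 6 muscle libraries (8 shared), 12 by fry (10 shared) and 11 by exact permutation of each index (9 shared); leaving out 1 library gave 14 (Restricted 1) to 26 (Control 6). Without the 6 libraries the mean log2 CPM difference reversed for fatty acid synthesis (−0.0204), the citric acid cycle (−0.0203) and cholesterol synthesis (−0.00428), none past the threshold (adjusted p 0.897, 0.801 and 0.897). The interaction was 0 genes by edgeR (871 at an unadjusted p under 0.05) and 1 by DESeq2. Without 1 library, the germ cell index by label ranged from 0.29 to 1.22, by diet from −1.03 to −0.10, and the epididymis index by diet from −0.97 to −0.15. With the replicate number as a block, 1388 genes changed with diet (37% higher; 1234 shared); the numbers pair no samples by the check (10 pairs, correlations −0.0895 to 0.134, 2 over 0.1, 1 control best correlated with its own number). Of 120 named genes called by diet, 0 reversed in any setting, DESeq2 kept 120, the integrity model 46, the 14 libraries 61, and 78 stayed called without each single library. These settings use the libraries that chose the genes, so the 0 reversals are no separate test. Label counts stayed within 1.5 times of 848. The median log2 fold change of all genes was 0.00881, and at most 0.0186 in an alternative. The cause was not tested where none is given. Depth limits genes near 1 CPM.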

Other observations

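The genes below and the lymphatic and blood endothelial lists were chosen after their values were seen. The 10 other lymphatic genes are the exception and were chosen without seeing theirs. Some of the smallest adjusted p-values by diet belonged to genes in no list. Egfr, the epidermal growth factor receptor, went from 110 ± 11.2 to 68.6 ± 6.63 CPM, C7, a complement component, from 319 ± 99.8 to 95.6 ± 34.5 CPM, and the collagen Col6a6, a neighbour of Col6a5 on chromosome 9, from 90.1 ± 17.1 to 46.0 ± 7.39 CPM (SD, n = 10 each). The metalloprotease Pappa, which frees insulin-like growth factors, fell by 1.45 on the log2 scale (edgeR adjusted p = 0.000125), and Fgl2 by 0.96. In the other direction, Ppp1r3b, which targets a phosphatase to glycogen, rose from 13.2 ± 2.26 to 32.9 ± 7.36 CPM (edgeR adjusted p = 6.3e-06), Bmp3 from 16.5 ± 5.24 to 42.0 ± 9.71 CPM, Pth1r, the parathyroid hormone receptor, from 15.6 ± 3.72 to 35.3 ± 10.8 CPM, and Mfge8 from 381 ± 48.2 to 576 ± 41.8 CPM. All of these had the same sign in libraries marked No alone and marked Yes alone, which is no separate test.

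Lower lymphatic markers under restriction were followed as a hypothesis, a lower share of lymphatic endothelial RNA. Mmrn1, Reln, Prox1, Flt4, Lyve1 and other genes already seen to fall gave 7 of 8 measured genes lower, 0 higher and a mean log2 fold change of −1.25, which is no independent evidence. The 8 measured genes chosen without seeing their values had a mean of −0.19 (camera p = 0.221), with 1 called higher and 1 lower. The hypothesis can thus neither be kept nor dropped on these counts. The 14 blood endothelial genes had a mean of −0.21 and a median of −0.12 (camera p = 0.0413, adjusted over 3 lists 0.062, and p = 0.494 with an estimated correlation), with Vwf, Plvap and Tek lower and 0 higher. In the 14 libraries without muscle transcripts their camera p was 0.00201, unadjusted and at the preset correlation.

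Xist, which is transcribed from an inactive X chromosome, had 70 counts in Control 5 and 52 in Restricted 1, and at most 11 in each other library.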
